A study of Homo sapiens with 10 samples.

How the data were processed

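RNA-seq was available for 10 libraries of polyadenylated RNA, 1 per genotype (wild type, B2M knockout) on each of days 0, 1, 3, 7 and 14. The deposited table holds raw counts per gene, whole numbers for 60605 Ensembl gene identifiers in 10 columns, and it was used as deposited. Per the submitters' processing notes, cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1 were used with the hg19 build. Their order, the annotation release and the strand setting of the counting are not given in the sources used here, so antisense, overlapping and paralogous genes (HLA, PSG) are uncertain. Libraries were random-primed and sequenced as paired ends, per the labels' protocols. Genotype and day came from the treatment label of each sample, which reads B2M knockout or control blank, and each column was matched to its sample by its name. The control samples are called wild type after their column names, which read WT. Gene symbols came from a GENCODE v29 table on GRCh38, used for names and gene order only, and 60463 identifiers (99.8%) matched. No coordinates are given. Library totals ran from 12.5 M to 20.6 M counts, so that 3 counts correspond to 0.13 to 0.25 CPM.

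Analyses were run in R 4.3.3. Genes were kept by filterByExpr with day as the group, leaving 17145 genes with at least 99.87% of the counts of each library. Counts were scaled by TMM (factors 0.806 to 1.12) and fitted with edgeR 4.0.16 by robust quasi-likelihood, with day as a factor plus genotype and 4 residual degrees of freedom. The common biological coefficient of variation was 0.178. F tests were made of the genotype term, of the 4 day terms together and of day 14 against day 0. A further fit with 3 residual degrees of freedom tested a genotype by log2(day + 1) term. Adjustment was by Benjamini and Hochberg at 0.05 over all genes tested. Log2 fold changes are the fitted ones, folds are their back-transforms, and genes with 0 counts in a group are given as bounds against a floor of 3 counts. Ratios with 1 to 3 counts in a group are given with a 95% exact conditional interval. The 34 gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and adjusted over the lists. Single days were described by log2 ratios with a prior count of 2 and, for lists, by percentile among 10000 random lists matched on mean expression.

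Named genes followed a rule fixed before the data were examined. It took B2M, the 12 largest called genotype differences in each direction with an average log2 CPM of at least 1 and 1 sign on all 5 days, and the 10 largest called changes from day 0 to day 14 in each direction with an average log2 CPM of at least 3 and 1 sign in both genotypes. It also took the 5 smallest p of the trend in each direction, the 3 largest ratios in each direction on each day with at least 10 CPM in 1 library, and the 4 members with the smallest p of each list. Genes of the Y chromosome, XIST and clone names were left out. Genes given as levels only (stromal, epithelial, endothelial, leukocyte and pluripotency markers) are members of the lists, not all named by that rule, and were picked after their values were seen, as were NR2F1 and CIITA.

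The steps were tested on counts simulated from a negative binomial distribution with the means and dispersions of the 17145 genes, with 200 genes changed. These 200 were drawn only from genes above a set mean count, so the shares recovered do not cover genes with few counts. For any change over days they were changed on day 14 alone, and for the trend the stated fold was reached on day 14. For the genotype step, 53.7%, 82.1% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 12 false calls. For day 14 against day 0 these shares were 5.97%, 37.3% and 97% with 5 false calls, for any change over days 4.48%, 41.8% and 92.4% with 27 false calls, and for the trend 0%, 2.99% and 47% with 10 false calls. In counts with no change the 4 steps called 1, 0, 4 and 0 genes. The share of false calls was above the nominal 0.05 for each step, slightly for day 14 against day 0 and most for any change over days and for the trend, so calls of these are less certain than their adjusted p.

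The alternatives tried were DESeq2 1.42.0, limma voom, RLE and upper-quartile scaling, no filter and a stricter filter, non-robust dispersion, leaving out each day's pair of libraries, no day term, a polynomial of time, a threshold of 2-fold, an untransformed day in the trend, other prior counts, camera with an estimated correlation and fry. With prior counts of 0.5 and 5 in place of 2, 13 of 60 values of single-day log2 ratios lay outside the counting interval, all 13 with a prior count of 5 and toward 0 (ACAN on day 1 from 8.85 to 7.54, SOX10 on day 0 from 8.37 to 7.06), so ratios against 0 or few counts depend on the prior count. Day 14 against day 1 was added after the data were seen. No column of the table was left out.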

Results

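The series held 10 RNA-seq libraries from human cells, 5 from wild-type cells and 5 from cells with a knockout of B2M, the gene of beta-2-microglobulin, which is the light chain of MHC class I. Each genotype gave 1 library on each of days 0, 1, 3, 7 and 14. The series title sets the question as how loss of B2M, made to lower immune recognition, alters membrane proteins and cytokines of human stem cells. The labels call the cells human pluripotent stem cells, and the library names of days 1 to 14 name H9, a human embryonic stem cell line. The growth text describes mesenchymal stromal cells placed in osteogenesis and chondrogenesis media, and it does not say which medium the libraries came from or what the days count. Library totals lay between 12.5 M and 20.6 M counts, with 15, 16.1, 14, 14.2 and 12.5 M for wild type and 15.4, 20.6, 13.8, 20.6 and 14.7 M for knockout on days 0, 1, 3, 7 and 14. No genotype was repeated within a day, so p-values measure only the spread between these libraries. Counting intervals and the lower bounds on fold changes cover counting error only.

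Many stromal markers were present in the libraries, and core pluripotency genes had few counts or none. FN1, which encodes fibronectin, took 7.31 to 13% of all counts, and COL1A1, the main chain of type I collagen, lay between 16400 and 43300 CPM (counts scaled to library size). The stromal surface markers NT5E (122 to 427 CPM), THY1 (38.3 to 84.6 CPM), ENG (96.7 to 193 CPM), CD44 (98.4 to 549 CPM) and PDGFRB (226 to 867 CPM) were present in all 10 libraries, while the stromal list members PRRX2 and VCAM1 had medians of 0.464 and 0.857 CPM. POU5F1 and NANOG, core factors of pluripotency, had 0 counts in every library, as did TDGF1, DPPA2, TERT, GDF3, PRDM14, UTF1, FGF4 and OTX2. Of 30 pluripotency genes, 14 had at most 3 counts summed over the 10 libraries, while others that are also expressed outside pluripotent cells had more, such as the Wnt receptor gene FZD7 (75.5 to 112 CPM) and the sialomucin gene PODXL (4.22 to 41.4 CPM). EPCAM, an epithelial adhesion molecule, lay between 0.901 and 2.41 CPM, the leukocyte gene PTPRC between 0 and 0.909 CPM and the endothelial gene PECAM1 between 0 and 1.2 CPM. Other members of the same lists were higher, among them the desmosome gene DSP (279 to 1190 CPM), the keratin genes KRT8 (44.9 to 400 CPM) and KRT18 (51.6 to 314 CPM), the growth factor receptor gene FLT1 (27.2 to 200 CPM) and the transcription factor gene RUNX1 (33.1 to 72.4 CPM). In the plot of principal components, the days were in order within each genotype along the component holding 37% of the variance, and the genotypes were apart along that holding 23.9%. Across genes, which are not independent replicates, each of the 5 knockout libraries was most like the wild-type library of its own day (Spearman rho 0.9623 to 0.9771).

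**Figure D1:**
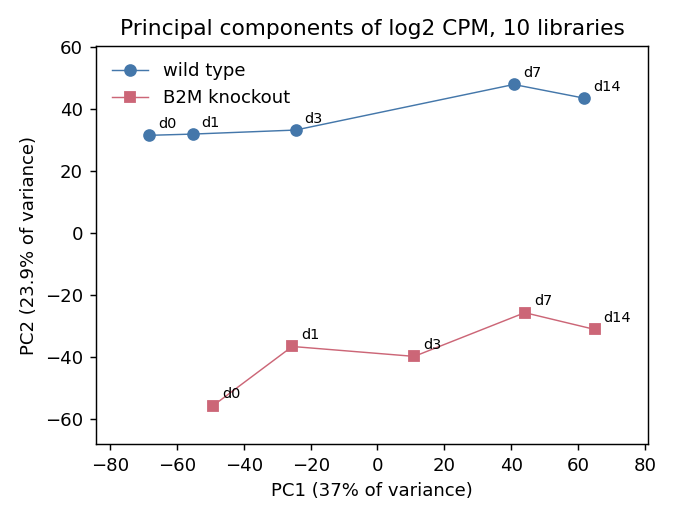
Principal components of log2 CPM, with 1 point per library, genotype shown by colour and the day written beside it. The axes are the components with 37% and 23.9% of the variance, and the wild-type libraries lie between 31.6 and 48 on the latter while the knockout libraries lie between -55.6 and -25.6.

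B2M was lower in the knockout library on all 5 days, at 94.8 ± 12.7 CPM (SD, n = 5 days) against 430 ± 133 CPM in wild type. Its log2 fold change was -2.13 with a standard error of 0.12 and an adjusted p of 4.85e-05 (edgeR quasi-likelihood test). The knockout level was 21%, 29.8%, 27.7%, 19.5% and 18.5% of wild type on days 0, 1, 3, 7 and 14, with 95% exact intervals reaching from 17.5% to 31.4% over the days. A transcript therefore remained in the knockout libraries, and gene counts do not show whether it encodes protein. The 11 measured neighbours of B2M on chromosome 15 had a median log2 fold change of 0.03 and were not called as a list (camera adjusted p = 0.485), although FRMD5, 1 of the 11, was 4.58-fold higher (adjusted p = 0.000429 with edgeR).

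**Figure D2:**
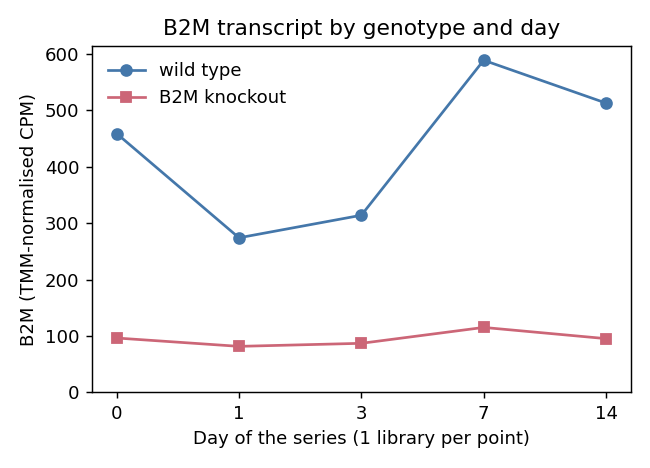
B2M in TMM-normalised CPM (vertical axis) by day (horizontal axis), with 1 library per point and the genotypes in separate lines. The knockout libraries lie between 81.4 and 115 CPM and the wild-type libraries between 274 and 589 CPM.

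Several genes of neural crest and Schwann cell precursors had counts in the knockout libraries and few or none in wild type, while the neural transcription factor gene NR2F1 (log2 fold change 0.06) and the neuronal gene STMN2 (-0.29), in the same list, were not called. SOX10, a master factor of the neural crest, had 2350 counts over the 5 knockout libraries and 0 over the wild-type ones, at least 666-fold higher against a floor of 3 counts over the group (adjusted p = 0.000125). FOXD3, an early neural crest factor, was at least 96.6-fold higher against the same floor. The glial gene S100B had 874 knockout counts and 1 wild-type count, a ratio of 743 (95% interval 133 to 29400), and CDH19, a cadherin of Schwann cell precursors, had 767 and 1, a ratio of 652 (117 to 25800). The neuregulin receptor gene ERBB3 was 29.6-fold higher (16.3 ± 7.82 against 0.516 ± 0.189 CPM, SD, n = 5) and the neurotrophin receptor gene NGFR 160-fold. Of 12 measured genes of the neural and neural crest list, 7 were higher, 0 lower and 5 not called, against 8 higher when adjusted over the list alone. The median log2 fold change was 2.54 and the camera adjusted p was 2.11e-08, or adjusted p = 0.108 with an estimated correlation. The called members included ZIC1, an ectodermal patterning factor with 294 knockout counts and 1 wild-type count (ratio 250, 44.5 to 9900), and NES, the intermediate filament nestin, at 4.12-fold (adjusted p = 0.0267). The NES call was lost without the pair of day 1, 3, 7 or 14 (adjusted p up to 0.0851), with no filter (0.141) and without the day term (0.208).

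Several cartilage genes were higher in the knockout libraries as well. ACAN, which encodes the cartilage proteoglycan aggrecan, lay at 56.4 ± 39.7 CPM in knockout and 0.0606 ± 0.0836 CPM in wild type (SD, n = 5), with a log2 fold change of 9.83, a standard error of 0.43 and an adjusted p of 4.85e-05. COL2A1, the collagen of hyaline cartilage, was 191-fold higher (standard error 0.31 on the log2 scale, adjusted p = 1.06e-05). Its level was low, with 46 counts in the knockout library of day 0 and 15 in that of day 14. HAPLN1, a link protein of cartilage matrix, rose 5.97-fold from a wild-type level of 86.2 CPM, and COL11A1, a fibrillar collagen of cartilage, 3.35-fold from 801 CPM, a call lost with a polynomial of day (adjusted p = 0.0565) and without the day term (0.18). Of 13 measured chondrogenic genes, 7 were higher, 0 lower and 6 not called, with 8 higher when adjusted over the list alone. The median log2 fold change was 1.74 and the camera adjusted p was 4.36e-06, or adjusted p = 0.394 with an estimated correlation. COMP, a cartilage matrix protein gene, was 2.5-fold higher (adjusted p = 0.034), a call lost without the pair of day 0, 1, 3 or 14 (adjusted p up to 0.196), with the polynomial (0.248) and without the day term (0.914). Of 11 osteogenic genes, 2 were higher and 0 lower, with the same counts when adjusted over the list alone and a camera adjusted p of 0.026 (adjusted p = 0.394 with an estimated correlation). These were DLX5, a bone and craniofacial factor with 341 knockout counts and 1 wild-type count (ratio 290, 51.7 to 11500), and SPP1, which encodes osteopontin, at 4.46-fold, a call lost with the polynomial (adjusted p = 0.0965) and without the day term (0.0947). The osteogenic list was not called without the day 1 pair (adjusted p = 0.0586) or the day 3 pair (0.095).

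**Figure D3:**
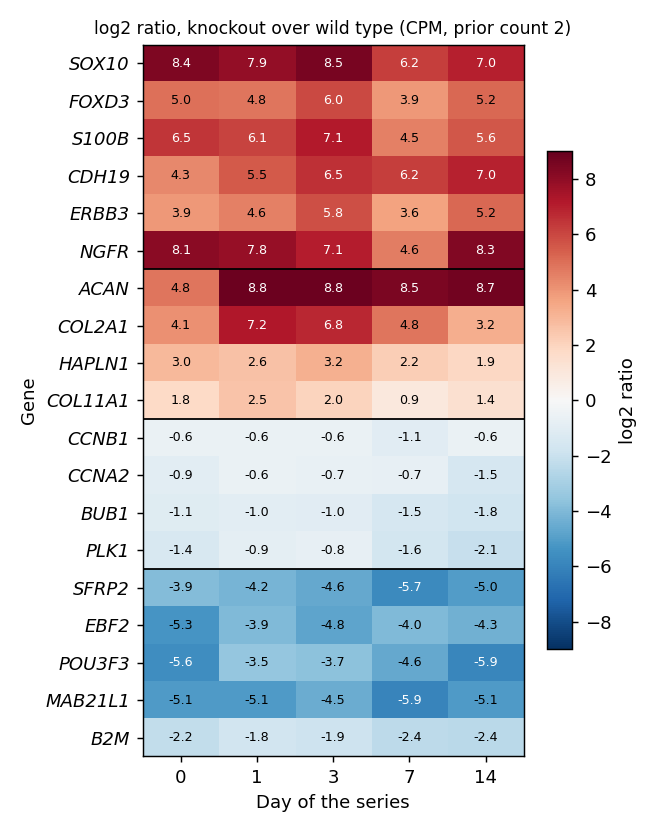
Log2 ratio of knockout to wild-type CPM (prior count 2) for 19 genes in the vertical direction and the 5 days in the horizontal direction, with the colour and the printed number giving the ratio from 1 library per genotype, of which large ones depend on the prior count. Neural crest, cartilage, cell cycle and knockout-lower genes stand in separate blocks, and each gene keeps its sign on all 5 days. The genes were picked from those named on the same data, so the constant sign is largely set by the selection.

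Growth factor and other genes with large differences joined these groups. TGFA, an epidermal growth factor receptor ligand, had 506 knockout counts and 3 wild-type counts (ratio 143, 48.8 to 698), PDGFB, a platelet-derived growth factor, was 12.1-fold higher, and BMP4, a bone morphogenetic protein, had 116 and 3 counts (ratio 32.9, 11 to 162). The 39 measured growth factors had 4 higher, 2 lower and 33 not called, with 7 higher and 3 lower when adjusted over the list alone, and were not called as a list by camera (adjusted p = 0.251) but were by fry (0.0291). LIMCH1, an actomyosin regulator, was 160-fold higher, and the transporter-like gene SLC35F1 had 1147 and 3 counts (ratio 325, 111 to 1580). The noncoding RNA LINC02367 had 431 and 1 counts (ratio 366, 65.4 to 14500). The 11 measured pluripotency genes had 2 higher, 0 lower and 9 not called, with 3 higher when adjusted over the list alone (camera adjusted p = 0.000462, or adjusted p = 0.375 with an estimated correlation). The called members were FOXD3 and SOX2, which are also neural crest and neural stem cell genes, and SOX2 had 183 knockout counts and 1 wild-type count (ratio 156, 27.6 to 6180).

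Lower in the knockout libraries were several developmental regulators. SFRP2, a secreted Wnt modulator, lay at 1.98 ± 2.03 CPM against 77.6 ± 85.4 CPM (SD, n = 5), a log2 fold change of -5.17 with a standard error of 0.21 and an adjusted p of 1.06e-05 (0.0742 without the day term). MAB21L1, a gene of eye and craniofacial development, had a log2 fold change of -5.74, EBF2, a factor of adipocyte and stromal precursors, -4.77 and POU3F3, a POU-domain factor, -4.55. The pregnancy-specific glycoprotein genes PSG4 and PSG5 had log2 fold changes of -6.68 and -5.96, and assignment of reads within this near-identical family is uncertain. ZNF667-AS1 had 2 knockout counts and 389 wild-type counts (ratio 0.00437, 0.000527 to 0.0159), and reads of this antisense gene cannot be told from those of its partner without strand. The thyroid hormone receptor gene THRB (-4.25), LINC01085 (-4.17), the potassium channel gene KCNK2 (-4.12), the tight junction gene CLDN11 (-3.45) and VAT1L (-3.02) completed the 12 largest. CLDN11 was not called without the day 3 pair (adjusted p = 0.054), with no filter (0.0879) or without the day term (0.0518), nor VAT1L without the day term (0.161), nor KCNK2 without the pair of day 1, 3 or 7 (adjusted p up to 0.064). Among 15 measured genes of the trophoblast and amnion list, 1 was higher, 5 lower and 9 not called, with 3 and 7 when adjusted over the list alone, and GATA3 and GATA2, zinc-finger factors of several lineages, fell by 2.90 and 1.56 on the log2 scale. That list was not called by camera (adjusted p = 0.0828) but was by fry (0.00708). The mesodermal factors FOXF1 (-2.06) and TBX3 (-1.65) were lower too, while KDR, a vascular endothelial growth factor receptor gene in the same list, was 10.9-fold higher. The 6 measured mesoderm genes had 1 higher, 3 lower and 2 not called, with 2 and 4 when adjusted over the list alone, and the list was not called by camera (adjusted p = 0.0538) but was by fry (0.0171).

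Genes of the cell cycle list were lower in the knockout libraries. BUB1 and PLK1, kinases of mitosis, fell by 1.26 and 1.27 on the log2 scale, and the cyclin genes CCNA2 and CCNB1 by 0.87 and 0.68, each lower on all 5 days. These 4 calls were lost with a polynomial of day (adjusted p = 0.0689 to 0.191) and without the day term (0.832 to 0.908). Without the day term the log2 fold changes of BUB1 and PLK1 were -1.12 and -1.09. Of 31 genes, 11 were lower, 0 higher and 20 not called, with 22 lower when adjusted over the list alone. The median log2 fold change was -0.68 and the camera adjusted p was 7.62e-14, or adjusted p = 0.394 with an estimated correlation. Ribosomal protein genes lay lower by a median of -0.19 with 0 of 63 called (0 when adjusted over the list alone; camera adjusted p = 1.29e-13, or adjusted p = 0.394 with an estimated correlation). The 13 mitochondrially encoded genes lay higher by a median of 0.20 with 0 called (0 when adjusted over the list alone; camera adjusted p = 0.00785, or adjusted p = 0.607 with an estimated correlation). The mitochondrial call was lost without the day 0 pair (adjusted p = 0.12) or the day 14 pair (0.0545) and with fry (0.185).

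HLA-B, a class I heavy chain, was 1.83-fold lower (adjusted p = 0.00134, and 0.0877 with the polynomial and 0.942 without the day term), and HLA-F, a nonclassical heavy chain, was 3.36-fold higher at 1.5 against 0.415 CPM (adjusted p = 0.0473), a call lost without the pair of day 0, 1, 3 or 14 (adjusted p up to 0.156), with limma voom (0.0528), non-robust dispersion (0.0509) or the polynomial (0.0503) and without the day term (0.114). The remaining 3 of 5 heavy chain genes were not called, with the same counts when adjusted over the list alone, and the list was not called (camera adjusted p = 0.651). Reads shared among HLA paralogs make these values uncertain. Of 15 antigen processing genes, 0 were higher and 2 lower, with 4 lower when adjusted over the list alone (camera adjusted p = 0.0177, or adjusted p = 0.394 with an estimated correlation). These were the immunoproteasome gene PSMB8 (-0.77) and the proteasome activator gene PSME2 (-0.42), whose calls were lost without the day 0, 1, 7 or 14 pair and, for PSME2, also the day 3 pair (adjusted p up to 0.0981). Without the day term they were not called either (0.325 and 0.311), nor was PSME2 with the polynomial (0.0559). Of 28 interferon-stimulated genes, 0 were higher and 3 lower, with 5 lower when adjusted over the list alone (camera adjusted p = 0.0196, or adjusted p = 0.62 with an estimated correlation). They were the guanylate-binding protein genes GBP1 (-2.05) and GBP2 (-1.73, adjusted p = 0.0756 without the day term) and IFITM2 (-0.56), a membrane restriction factor gene that was not called without the day 0, 7 or 14 pair (adjusted p up to 0.114) or without the day term (0.183). The interferon and antigen processing lists were not called without the day 0 pair (adjusted p = 0.136 and 0.0982) or the day 14 pair (0.257 and 0.0628), nor with fry (0.217 and 0.0757).

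Among class II genes, 2 chain genes with few counts were higher in the knockout libraries, while CIITA, the class II transactivator gene, had a log2 fold change of -0.02. HLA-DRA had 55 knockout counts and 0 wild-type counts, at least 15.6-fold higher against 3 counts over the group (adjusted p = 0.0347, and 0.0523 without the day 14 pair), and HLA-DRB1 was 12.5-fold higher at 1.14 CPM, a call lost with the polynomial (0.107) and without the day term (0.179). Of 7 class II genes, 2 were higher and 0 lower, with 4 higher when adjusted over the list alone (camera adjusted p = 0.000578, or adjusted p = 0.394 with an estimated correlation). CD274, the checkpoint ligand PD-L1, was 3.07-fold lower (adjusted p = 0.576 without the day term), and the 21 natural killer cell ligands and checkpoint genes had 1 higher, 1 lower and 19 not called (2 and 2 when adjusted over the list alone; camera adjusted p = 0.776). The higher gene of that list was CD55, with a log2 fold change of 0.82 (edgeR adjusted p = 0.0496). Among 36 cytokine and chemokine genes, 2 were higher, 1 lower and 33 not called, with the same counts when adjusted over the list alone (camera adjusted p = 0.46). The lower gene was TSLP, an epithelial cytokine gene, with a log2 fold change of -2.29 whose call was lost without the day 7 or day 14 pair (adjusted p up to 0.0654). IL16, among the 2 higher, had a log2 fold change of 1.56 (edgeR adjusted p = 0.046). Of 21 integrin genes, 1 was higher, 1 lower and 19 not called (2 and 1 when adjusted over the list alone; camera adjusted p = 0.251).

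Over all 17145 tested genes, 1016 differed between genotypes in the edgeR quasi-likelihood test with day as a factor, 647 higher and 369 lower in knockout, and 992 of them kept 1 sign on all 5 days. The test selects genes whose difference varies little between days, so this share is largely set by the selection. Of the 34 gene lists, 10 were called by camera with a preset correlation and 0 with an estimated one. The estimate was -0.0791 for the neural and neural crest list, below the preset 0.01, so a higher correlation does not explain that loss. It was above 0.01 for the other called lists, but their losses cannot be put down to correlation alone. For p53 targets, with an estimate of 0.0105 near the preset, the unadjusted camera p also rose, from 0.0568 to 0.131. The number of genes was 316 without the day term, all of them among the 1016, and between 607 and 913 when the pair of 1 day was left out.

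The largest rises from day 0 to day 14 with the same sign in both genotypes included genes of matrix proteins. ASPN, which encodes the matrix protein asporin, and OMD, osteomodulin, had 0 counts in both day 0 libraries and were at least 763-fold and 411-fold higher on day 14 against 3 counts over the group. ELN, the gene of elastin, had a log2 change of 8.90 with a standard error of 0.96, TMEM119, an osteoblast membrane protein gene, 8.57 and SFRP2 6.67. COL21A1, a collagen gene, changed by 7.37, CORIN, a serine protease gene, by 6.97, GPNMB, a glycoprotein gene of osteoblasts and macrophages, by 6.33, PLXDC2 by 5.86 and the collagen-binding integrin gene ITGA10 by 5.66. These log2 changes are averaged over the genotypes. For PLXDC2 the rise was larger in wild type, by the daily ratios given with the trend. ALPL, the alkaline phosphatase of mineralising cells, changed by 4.90 with a standard error of 0.50 (adjusted p = 0.000806). The calls of COL21A1 and TMEM119 were lost with limma voom (adjusted p = 0.0641 and 0.0699) and, like those of OMD and PLXDC2, with no filter (0.0865, 0.0571, 0.0938 and 0.0806). Of 11 osteogenic genes, 4 were higher, 1 lower and 6 not called, with the same counts when adjusted over the list alone, and the list was not called by camera (adjusted p = 0.169) but was by fry (0.0154). Of 13 chondrogenic genes, 4 were higher, 2 lower and 7 not called, again with the same counts (camera adjusted p = 0.67).

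Hypoxia-inducible and glycolytic genes fell from day 0 to day 14. ALDOC and ENO2, glycolytic enzymes, had log2 changes of -4.56 and -4.52, PDK1, a kinase that limits pyruvate oxidation, -3.67, BNIP3, a mitophagy receptor gene, -3.24 and PGK1, a glycolytic kinase gene, -3.00. Of 25 genes, 23 were lower, 0 higher and 2 not called, also when adjusted over the list alone (median -2.31, camera adjusted p = 4.9e-19, or adjusted p = 0.081 with an estimated correlation). The centred list level was 1.51 in wild type and 1.49 in knockout on day 0, and already -0.357 and -0.306 on day 1. STC1, a calcium-regulating hormone gene, had a log2 change of -4.57, the smooth muscle coactivator gene MYOCD -4.75, the kinase gene WNK4 -4.54, the interleukin receptor gene IL7R -4.47 and TCIM -4.19. WNK4 and IL7R were not called with no filter (adjusted p = 0.075 and 0.0656).

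The inflammatory genes CXCL8, IL6 and CXCL1 also fell, with log2 changes of -7.64, -5.80 and -5.24, although CXCL8 and CXCL1 were not called with no filter (adjusted p = 0.062 and 0.112). CXCL8, a neutrophil chemokine, stood at 2990 CPM in the wild-type library of day 0, at 105 CPM in the knockout library of that day and at 1.93 to 15.4 CPM in the 8 later libraries. Of 36 cytokine genes, 5 were higher, 12 lower and 19 not called, with 5 and 13 when adjusted over the list alone (camera adjusted p = 0.0378, or adjusted p = 0.541 with an estimated correlation and 0.0607 with fry). The day 0 libraries are named in another way, and the labels do not say whether they share line, batch and culture with the later ones, so changes from day 0 cannot be separated from such a difference. Day 14 was therefore also set against day 1, a comparison chosen after the data were seen, which called 3684 genes. Of these, 1997 were also called against day 0, whatever their direction. IL6 and TCIM then had log2 changes of 1.07 and 0.34, neither called (adjusted p = 0.303 and 0.738), the calls of CXCL8 (-0.28), CXCL1 (-0.87), ENO2 (-0.70), STC1 (-0.86) and TMEM119 (3.97) were lost, and the cytokine list had the opposite direction but was not called (adjusted p = 0.198).

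The cell cycle list was lower on day 14 than on day 0, with 20 of 31 lower, 0 higher and 11 not called, and 23 lower when adjusted over the list alone (median -1.57, camera adjusted p = 8.63e-09, or adjusted p = 0.479 with an estimated correlation). Its centred level was higher on day 1 than on day 0, at 1.63 against 0.69 in wild type and 1.01 against 0.166 in knockout, and stood at -0.658 and -1.71 on day 14. PLK1 had a log2 change of -2.88 from day 0 to day 14. Interferon-stimulated genes had 8 higher, 0 lower and 20 not called of 28, with 9 higher when adjusted over the list alone (camera adjusted p = 0.00159, or adjusted p = 0.541 with an estimated correlation and 0.0607 with fry), among them the antiviral gene IFIT2 (3.15) and the transcription factor gene STAT2 (1.39). HLA-B fell by 2.71 on the log2 scale from day 0. Against day 1 its log2 change was -0.39, which was not called. The keratin genes KRT8 (-2.25) and KRT18 (-2.10) were among the 7 lower, 1 higher and 7 not called of 15 trophoblast and amnion genes (1 and 8 when adjusted over the list alone; camera adjusted p = 0.00124, or adjusted p = 0.479 with an estimated correlation). Smooth muscle genes had 7 lower, 0 higher and 9 not called of 16 (11 lower and 2 higher when adjusted over the list alone; camera adjusted p = 0.00493, or adjusted p = 0.479 with an estimated correlation). BMP and TGF-beta targets had 8 lower, 1 higher and 9 not called of 18 (the same when adjusted over the list alone; camera adjusted p = 0.00656, or adjusted p = 0.479 with an estimated correlation), including ID3 (-2.54), a BMP-induced inhibitor of differentiation, and TGFBI (-3.46), a TGF-beta-induced matrix gene. Against day 1 the smooth muscle (adjusted p = 0.967) and BMP and TGF-beta (0.137) lists were not called. All 13 mitochondrially encoded genes were higher (median 1.29, also 13 when adjusted over the list alone; camera adjusted p = 8.63e-09, or adjusted p = 0.479 with an estimated correlation), and their share of counts ran from 0.87 to 3.46% over the 10 libraries. Ribosomal protein genes had 55 of 63 lower and 0 higher, with 61 lower when adjusted over the list alone (median -0.61, camera adjusted p = 1.26e-19, or adjusted p = 0.479 with an estimated correlation).

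The edgeR test called 3980 genes for any change over days and 3937 for day 14 against day 0, 1922 higher and 2015 lower. Over all 17145 genes, 72% had the same sign of change in both genotypes. The share was 99.7% among the called genes, which were selected on the average of the genotypes. The changes of the genotypes had a Pearson r of 0.673 and a Spearman rho of 0.608 across genes, which are not independent replicates. Genes called for both genotype and day numbered 448. Leaving out the day 1 pair lowered the count for any change over days to 2217.

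**Figure D4:**
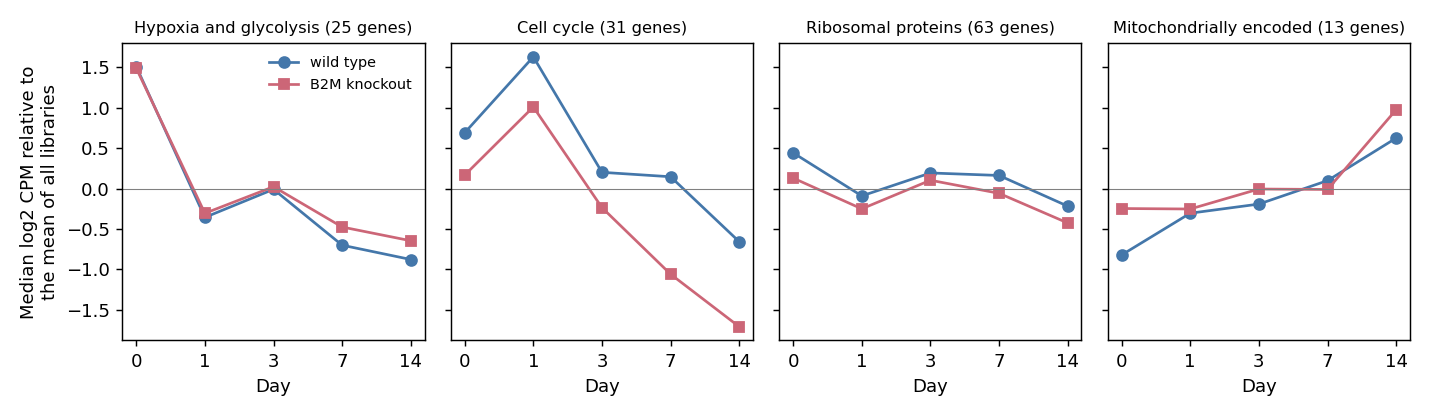
Median log2 CPM of gene lists relative to the mean of all libraries (vertical axis) by day (horizontal axis), with 1 library per point. The panels show the hypoxia and glycolysis, cell cycle, ribosomal protein and mitochondrially encoded lists, with the genotypes in separate lines. The cell cycle list lies at 1.63 in wild type and 1.01 in knockout on day 1, and at -0.658 and -1.71 on day 14.

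Within single days no test was possible, with 1 library per genotype. On day 0, CRHBP, a binding protein of corticotropin-releasing hormone, had 923 knockout counts and 0 wild-type counts, at least 277-fold higher against 3 counts per library, while VCAM1, a cytokine-induced adhesion molecule, lay at 1.49 against 67.1 CPM and SLC7A2, an arginine transporter gene, at 3.49 against 209 CPM. ACAN was at least 346-fold higher on day 1 and 231-fold on day 14 against the same floor. On day 7, COL15A1, a basement membrane collagen gene, had 245 and 1 counts, and CALCR, the calcitonin receptor gene, 278 and 2. CLDN11 lay at 3.95 against 145 CPM on day 7 and 2.5 against 81.9 CPM on day 14. Among genes with at least 10 CPM, the numbers at least 2-fold higher and lower in knockout were 284 and 324, 203 and 112, 248 and 114, 229 and 172, and 309 and 246 on days 0, 1, 3, 7 and 14. The median of the neural crest list exceeded those of all 10000 random lists matched on expression on each day, and so did that of the chondrogenic list.

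No gene passed the test of a trend in the knockout difference, and the values of those with the smallest p follow. PLXDC2 had log2 ratios of 5.47, 5.67, 4.55, 2.08 and 1.43 on days 0, 1, 3, 7 and 14, and NOTCH3, a Notch receptor gene of mural cells, -0.676, 0.536, 0.596, 1.52 and 1.95. SULF2, a heparan sulfate editing enzyme, ran from 2.07 to -0.836. The edgeR test of genotype by log2(day + 1) called 0 genes (smallest adjusted p = 0.0758, 1748 genes at an unadjusted p under 0.05), limma voom called 0 and DESeq2 143. Without the day 0 pair the edgeR count was 170.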

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

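Chosen only after the result was seen were the tests of a depth difference, a fixed cell population, a line difference, admixed wild-type cells (both tests), pseudogenes and chromosome segments. The counts over other splits of the libraries were planned.

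The cell cycle list passed the test of a trend in the genotype difference, with a median of -0.175 per doubling of day + 1 and a camera adjusted p of 0.000419, a call lost with an estimated correlation (adjusted p = 0.859). Its daily medians were -0.678, -0.6, -0.453, -1.11 and -1.01 on days 0, 1, 3, 7 and 14. No single member was called over all genes (1 lower when adjusted over the list alone), and the daily medians were nearer 0 on day 3 than on day 0.

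The higher neural crest and cartilage genes of the knockout libraries were weighed against a difference in depth, against an admixed cell population and against a line difference. Knockout libraries held 1.18 times the counts of wild type, while the median fold of the 14 called members was 32.2, which depth does not account for. These folds were scaled to library size, so depth was already divided out of them. Cells of 1 fixed profile mixed in at changing shares would move these genes together. Their log2 changes from day 0 to day 14 in knockout spanned 5.32, from NES (-2.64) to ACAN (2.68). This span argues against a fixed profile only if the day 0 libraries share line, batch and culture with the later ones. The labels do not say whether they do, so a fixed profile and a population that itself changes both stay open. Both lists were higher on 5 of 5 days, and a difference between the lines other than the edit cannot be told apart from the knockout, because the labels name no clone and no further line of either genotype. The genotypes may therefore differ by the edit or by how each line was derived.

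The transcript left in the knockout libraries was weighed against wild-type cells mixed in. If such cells made up the B2M fraction of 18.5 to 29.8%, genes of wild-type cells could not lie below it, and the bound set was over 10 genes below it on all 5 days. With at least 100 counts in every wild-type library 2 genes of 9163 did, and a further test with at least 300 summed wild-type counts, made after that value was known, found 6 of 11845, so neither met the bound. A bound lowered to 3 genes, tried once both values were known, was withdrawn for that reason. The 6 were ZNF667-AS1 (0.437% of wild type), PSG4 (0.892%), MAB21L1 (1.81%), SFRP2 (2.55%), EBF2 (3.91%) and POU3F3 (4.4%). These values go against wild-type cells of unchanged profile as the whole source of the B2M transcript. With the bound unmet in both tests, a smaller share of such cells is left open. So are admixed cells of a changed profile, beside a transcript surviving the edit.

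The absence of pluripotency transcripts was weighed against reads lost to pseudogenes. Of the 14 genes with at most 3 counts, 8 have no pseudogene named after them, so reads lost to a named pseudogene do not account for these 8. POU5F1 and NANOG are not among the 8, with 6 and 11 named pseudogenes, so this test does not cover them. Reads shared with other near-identical genes, such as those of LEFTY1 with LEFTY2, were not tested. Whether the cells had been differentiated before day 0 was not tested, and the labels do not state it.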

How the results depend on the processing

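Day 14 against day 1 was chosen after the data were seen, and the other alternatives were planned. Of the 55 named genotype genes that were run under the alternatives, 32 kept their call under each of up to 14 and 0 changed direction. These genes were named for their large or small-p differences in the same libraries, so the 0 is largely set by the selection. Of 34 named day 14 genes, 21 kept theirs under up to 11 alternatives, and against day 1 the log2 changes of IL6 (1.066, adjusted p = 0.303) and TCIM (0.3407, 0.738) had the opposite sign but were not called, and the cytokine list likewise (adjusted p = 0.198). The genotype count was 316 without the day term, 651 at 2-fold or more and 607 to 913 on leave-one-out, against 1016. It stayed within 1.5 times (727 to 1302) for DESeq2, voom, other scalings, filters, non-robust dispersion and the polynomial. Any change over days gave 2217 to 3818 genes on leave-one-out. The trend count of 0 became 143 with DESeq2, 50 with no filter and 0 to 170 on leave-one-out, the last without day 0. With an estimated correlation 0 lists were called for genotype and 0 for day 14, and fry called 13 for genotype, 7 of them shared with the 10 by camera, and 15 for day 14 against 9 by camera, testing whether a list moves and not whether it exceeds other genes. Leaving out day 0 or day 14 gives no value for day 14 against day 0. Day 14 against day 1 called 3684 genes, 1997 of them also among the 3937 against day 0, whatever their direction. Depth limits genes near the floor of 3 counts. Without the day term, differences between days count as residual spread. The log2 fold changes of HLA-B (-0.875 to -0.807) and CD274 (-1.62 to -1.45) then moved little while their calls were lost. The cause of the other shifts was not tested, beyond fewer libraries or genes tested where an alternative removes them.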

Other observations

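The test of chromosome segments was chosen after the result was seen, and the split counts were planned.

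The interferon-stimulated list had median log2 ratios of knockout to wild type of -0.988, 0.139, -0.138, 0.0252 and -0.895 on days 0, 1, 3, 7 and 14. On days 0 and 14 these lay below all 10000 random lists. The cytokine list lay at -0.617 on day 0 and 0.24 on day 1, and the stromal marker list at -0.321 on day 0 and 0.103 on day 1. The epithelial junction list, with 3 of 16 genes higher and 1 lower in knockout over the 5 days (camera adjusted p = 0.0828, fry 0.014), had its largest daily median on day 7 at 0.79. Natural killer cell ligands and checkpoint genes lay at -0.219 on day 1 and 0.524 on day 14. These daily values come from 1 library per genotype and were not tested between days.

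A gained or lost chromosome segment in 1 line would shift neighbouring genes together. Over 8728 runs of 50 neighbouring genes among 9806 expressed autosomal genes, ordered on GRCh38, the largest median difference was 0.175 in size and medians ran from -0.17 to 0.12, which argues against a segment of that length carried by most cells. Smaller or subclonal segments are not excluded. The list of 14 genes of chromosome 20 band q11.21, a region often gained in pluripotent lines, had a median of 0.05 (camera adjusted p = 0.5).

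For the genotype comparison, 1 of 100 splits of the 10 libraries into 5 and 5, the real one, gave as many genes, with a real value of 1016 and a highest other of 49. Of the others drawn, most keep both libraries of some days together and so do not match the pairing by day. Only 14 of the splits drawn, the real one included, part all 5 pairs, and the highest other count among these was 0, but they are too few for a share under 0.05. For the trend term the real count was 0, which each of the 79 splits that could be fitted, 79 of 79, reaches by construction, so this count says nothing about chance. The highest other was 293, and splits that put wild-type libraries early and knockout libraries late turn the genotype difference into a trend.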
